A study of Mus musculus with 2 samples.

How the data were processed

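Poly(A) RNA from thigh skeletal muscle of B6C3F1 mice aged 26 months was sequenced in 2 libraries, 1 from the control group and 1 from the calorie restriction group (CR). Per the labels' protocols, RNA was selected from 10 µg of total RNA, broken to fragments near 200 nt, copied with random primers and made into paired-end libraries with the Illumina mRNA-Seq kit, and reads were 76 bp long. The kit as described does not mark the strand of origin, so overlapping genes on opposite strands cannot be told apart. The grouping follows the diet given in the labels. Whether each library pooled several mice is not given in the sources used here.

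Per the submitters' processing notes, the authors used TopHat 1.2.0, Cufflinks and Cuffdiff with the mouse build mm9; the versions of the latter tools, their options, the gene annotation and any filters are not given in the sources used here. The deposited values are FPKM per locus, fragment counts scaled by transcript length and by the library's mapped fragments, per the file headers, with a column for each library. The table holds 23672 loci, of which 10782 carry a gene name and 12890 (54.5%) do not. Coordinates are those of the table, read as 1-based with both ends included, since the end minus the start equals the RefSeq gene length minus 1 at 1544 loci and that length at 47.

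The lowest deposited value is exactly 1. In the control column 98 of 101 values between 1 and 2, 59 of 68 between 10 and 11 and 40 of 46 between 100 and 101 carry more than 6 significant digits, and 0 of 77 between 2 and 3, 0 of 73 between 11 and 12 and 0 of 54 between 101 and 102 do. These are the digits of 6-digit values to which 1 was added, so 1 was subtracted to obtain FPKM. The offset is inferred from the digits and is not stated in the sources used here. The columns sum to 12758500 FPKM in the control library and 13608800 FPKM in the CR library, a scale that is high for FPKM and not explained in the sources used here, so FPKM are compared between these libraries and not with other data. The depth of each library is unknown: the values are not whole multiples from which reads could be recovered, and so no counting interval is given. Loci listed at 0 numbered 1615 in the control library, 3691 in the CR library and 801 in both. Of the last, 9 are named and include Ttn, Neb and Myh2, abundant in muscle, so that 0 can be a failed estimate. No fold is given for a gene listed at 0 in a library.

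Loci with a single gene symbol were used, loci of the same symbol were summed, and 234 loci that merge several symbols were left out, giving 10543 genes. Per gene the log2 ratio of CR FPKM + 1 over control FPKM + 1 was computed with no further scaling, which equals the log2 ratio of the deposited values. Genes with a mean of at least 1 FPKM were kept (10533), and those with a ratio of at least 2-fold were counted. On the scale of this table the filter at 1 FPKM removes few genes, which led to the stricter filters named here. With 1 library per group there is no test across samples and no p-value. To describe a gene list, the percentile of its median log2 ratio was taken among the medians of 10000 random lists of the same size, matched gene by gene on the decile of mean FPKM (seed 1). A list with at least 5 measured genes stood apart below percentile 2.5 or above percentile 97.5. The 42 lists cover muscle fibre types, metabolism, growth and stress pathways and the other cell types a muscle sample can hold. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used, and matplotlib 3.10.9 for the plots. Transcript lengths and GC content came from the mouse annotation of a later build by gene symbol and were found for 99.2% of genes; no coordinates of that build were used.

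The samples' groups, the lists, the thresholds, the first set of alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names the 12 genes with the highest and the 12 with the lowest log2 ratio among those with a mean of at least 5 FPKM, leaving out symbols of predicted genes and pseudogenes, up to 3 genes of each list with the largest ratios and its most abundant gene, and the 5 most abundant genes; of lists with under 5 measured genes it names the most abundant gene. Some genes that the rule takes are not reported here. As the highest and lowest ratios all belonged to genes listed at 0 in a library, the 12 highest and 12 lowest genes with a mean of at least 300 FPKM and above 0 in both libraries were added after the values were seen. Other genes named outside these rules, among them Sln, Fasn, Fabp4, Gpam, Runx1, Chrna1, Mybph, Myog, Mcpt4 and Myh6, were chosen after their values were seen.

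The alternatives chosen beforehand were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at 10 FPKM, centring on the median gene, rescaling to equal sums without the 50 most abundant genes, and keeping the largest locus of a symbol. Added after the data were seen were filters at 100 and 300 FPKM, leaving out genes at 0 in either library, a pseudocount of 50 FPKM, and random lists matched also on transcript length or on GC content. In these matched lists mean FPKM was divided into 5 groups in place of deciles, and length or GC content into 5 groups. Isoform shares, foreseen in the design, were not analysed here, as the values are per locus. The procedure was tested on simulated data for CR against control with 10533 genes and lists of 20 genes: 4% of 400 random lists fell outside the range, 100% of lists with a planted shift of 1 on the log2 scale and 87% with a shift of 0.5 were recovered, and 95% of genes planted 4-fold higher and 94% of those planted 4-fold lower passed 2-fold. The simulated ratios had normal noise of a chosen size, independent between genes, and no values at 0. These rates follow from that noise and need not hold for the 2 libraries.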

Results

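Poly(A) RNA was sequenced from thigh skeletal muscle of 26-month-old mice of the hybrid strain B6C3F1. The control group ate the control diet. The other group was kept on calorie restriction (CR), in which the mice ate 40% fewer calories over 25 months on an enriched diet. Each group is represented by 1 library, so there are no replicates and no difference between the libraries has a replicate check. How many mice contributed to each library is not given in the sources used here. The values are FPKM per gene locus on the mouse build mm9, the depth of each library is unknown, and 10543 genes with a single symbol were listed among 23672 loci. Log2 ratios are CR over control on the log2(FPKM + 1) scale, and folds are the same ratios on the linear scale, which understates differences of genes with low values. Where a pair of FPKM values is given, the control library comes first and the CR library second.

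The comparison asks which transcripts of aged muscle differ between the restricted and the control diet. The CR library had more transcript of slow-twitch sarcomere genes, of fatty acid synthesis enzymes and of adipocyte genes, and less of genes that muscle expresses when its nerve supply is lost and of the main atrophy ubiquitin ligases. Myh7, the slow myosin heavy chain, was listed at 8953 FPKM in the control library and 81978 in the CR library, a fold of 9.16. Acly, which makes cytosolic acetyl-CoA for lipid synthesis, stood at 181 and 3887 FPKM, a fold of 21.4. Gadd45a, a stress gene induced by denervation, stood at 2088 and 279.9 FPKM, 7.44-fold lower in the CR library. Trim63, the ubiquitin ligase MuRF1, stood at 4762 and 1738 FPKM, 2.74-fold lower in the CR library.

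Of 10533 genes with a mean of at least 1 FPKM, 844 were at least 2-fold higher in the CR library, 1124 were at least 2-fold lower and 8565 (81.3%) lay within 2-fold. Among the higher genes 239 were listed at 0 in the control library, and among the lower genes 450 were listed at 0 in the CR library. A value of 0 can be a failed estimate in this table: Ttn and Neb, which encode the giant sarcomere proteins titin and nebulin, were listed at 0 in both libraries. Higher genes made up 42.9% of those past 2-fold, and 59.5% (179 higher, 122 lower) of those with a mean of at least 300 FPKM. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) between the libraries was 0.75 for all 10543 genes and 0.90 for the 9846 above 0 in both. The 5 most abundant genes were Acta1, skeletal actin (372424 and 354522 FPKM), Mylpf, the fast regulatory light chain (146936 and 283395), Gm14492 (179152 and 234258), Tnnc2, fast troponin C (133102 and 246497), and Tnnt3, fast troponin T (103936 and 171817). Gm14492 overlaps Tnnt3 on the opposite strand, and the kit as described does not mark strand, so its value is uncertain.

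**Figure D1:**
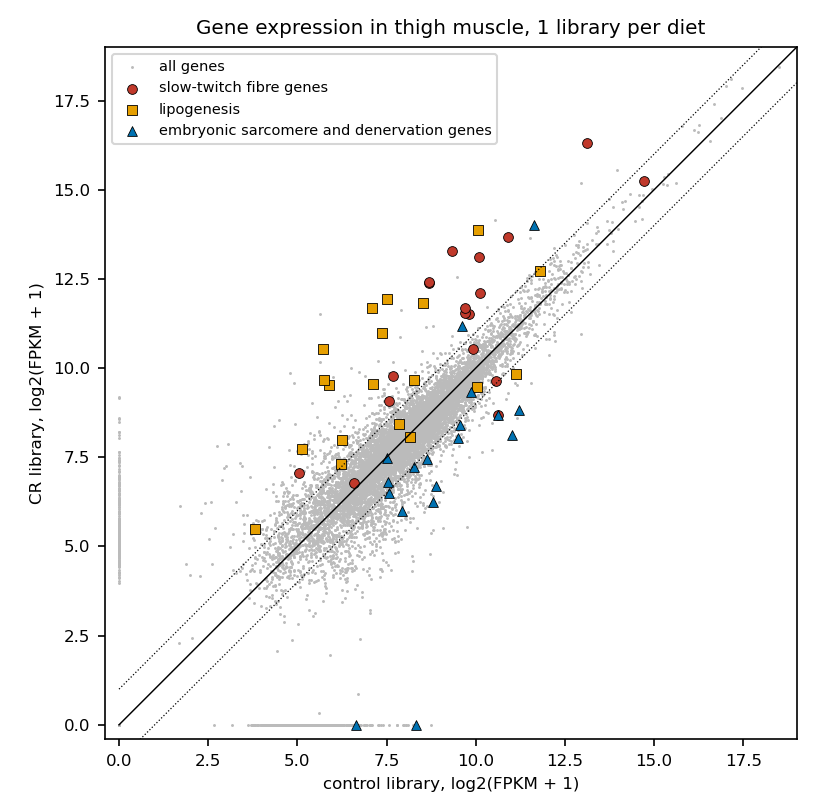
Log2(FPKM + 1) of each gene in the control library (horizontal axis) and the CR library (vertical axis), 1 library per diet, with 3 gene lists coloured; the solid line marks equal values and the dotted lines 2-fold differences. In the slow-twitch list 13 of 18 genes and in the lipogenesis list 14 of 19 genes lie above the upper dotted line, and 13 of 18 denervation genes lie below the lower one.

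The 12 genes with the highest and the 12 with the lowest log2 ratios were all listed at 0 in one of the libraries, so they have no fold. On the higher side were S100a8, a calcium-binding protein of neutrophils (0 and 581 FPKM), Car5b, a mitochondrial carbonic anhydrase (0 and 567), and Psme2, a proteasome activator subunit (0 and 386). The others there were Chn1 (0 and 381), Rpl21 (0 and 358), Dcpp2 (0 and 297), Actr6 (0 and 294), the small nuclear RNAs Rnu11 (0 and 276) and Rnu12 (0 and 201), Uts2d (0 and 198), Ucp1 (0 and 189) and the fructose transporter Slc2a5 (0 and 179). Among those on the lower side were the keratin Krt8 (425 and 0), Klk1b22 (319 and 0), Zfp874b (301 and 0), Vaultrc5 (273 and 0), and Atpbd4 (262 and 0). Also there were Emb (262 and 0), Fez1 (253 and 0), Cep97 (249.8 and 0), the matrix protein Tnc (223 and 0), Ttll5 (220.0 and 0) and Papd4 (187 and 0). Among genes above 0 in both libraries with a mean of at least 300 FPKM, a rule chosen after the values were seen, the highest ratios were those of Sbpl (chromosome 17, 24090052 to 24092257; 48.3 and 2924 FPKM, a fold of 59.4) and the protein kinase A subunit Prkar2b (chromosome 12, 32643344 to 32746144; 26.9 and 921, 33.0). Next came the fatty acid elongase Elovl6 (chromosome 3, 129235304 to 129341411; 51.7 and 1488, 28.3) and the liver-type glycogen phosphorylase Pygl (chromosome 12, 71291802 to 71328670; 29.0 and 771, 25.7). The other 8 were Thrsp, Retn, Acly, Myl2, Slc25a1, Scd1, Orm1 and Tnni1, with log2 ratios from 3.74 for Tnni1 to 4.60 for Thrsp. The lowest ratio by that rule was that of Dkk3, a secreted Wnt modulator (chromosome 7, 119258433 to 119302591; 859 and 45.3 FPKM, 18.6-fold lower in the CR library). Gadd45a, Igfn1, Zmynd17, Rrad, Krt18, Cpne2, Ces2c, Ankrd1, Trp63, Dupd1 and Napb followed, with log2 ratios from -2.89 for Gadd45a to -2.26 for Napb.

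Slow-twitch sarcomere genes stood higher in the CR library. Of 18 measured genes, 13 were at least 2-fold higher, 1 was at least 2-fold lower and 4 lay within 2-fold. The ventricular and slow light chain Myl2 (chromosome 5, 122550896 to 122556864) stood at 644 and 10019 FPKM and slow troponin I, Tnni1 (chromosome 1, 137695837 to 137707566), at 408 and 5479.8. Slow troponin C, Tnnc1 (chromosome 14, 32021498 to 32024915), stood at 414 and 5346 and Myh7 (chromosome 14, 55589521 to 55613438) at 8953 and 81978. The lower gene was Sln, sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum, at 1589.5 and 407 FPKM; it is also in the denervation list. The median log2 ratio of the slow list was 1.99, a fold of 3.96, at percentile 100 among 10000 random lists matched on mean FPKM. Fast-twitch genes stood closer together in the libraries: 1 of 14 was at least 2-fold higher, 0 were at least 2-fold lower and 13 lay within 2-fold. The fast list had a median log2 ratio of 0.54 at percentile 99.87. The fast gene past 2-fold was Tnni2, fast troponin I (56111 and 114033 FPKM), while Mylpf (0.95) and Tnnc2 (0.89) lay just under it on the log2 scale. Myh2 and the merged locus of Myh1, Myh3, Myh4 and Myh8 on chromosome 11 (66891802 to 67122135) were listed at 0 in both libraries, so the fast myosin heavy chains could not be compared. Myh6, the neighbour and close paralog of Myh7, stood at 1479.9 and 18349 FPKM, and its value is uncertain because the copies can share reads. White adipocyte markers were higher in the same library, with a median log2 ratio of 1.93.

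**Figure D2:**
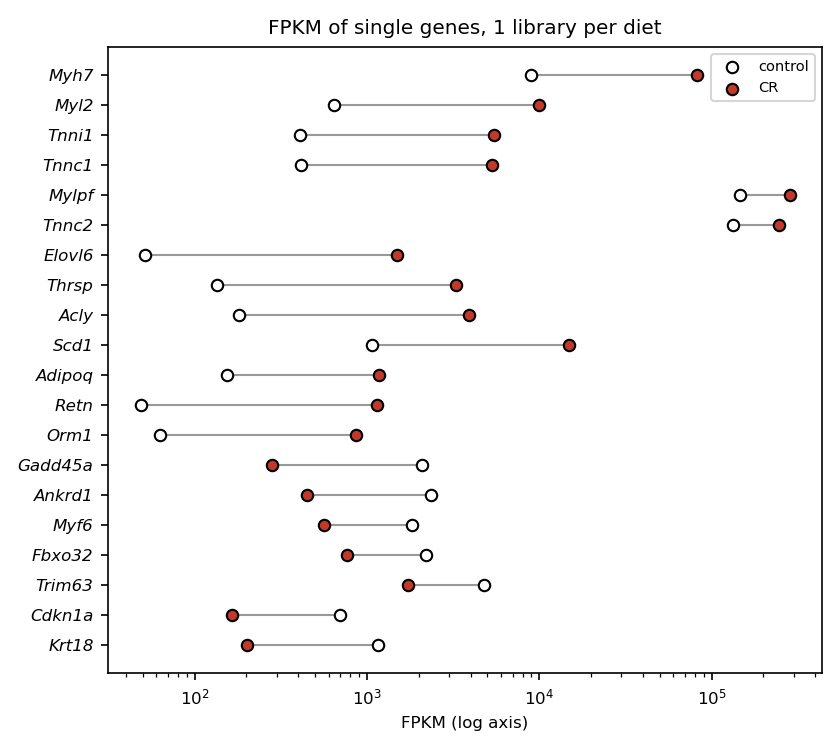
FPKM of 20 single genes on a log axis, with open circles for the control library and filled circles for the CR library, 1 library each. The slow-twitch genes Myh7, Myl2, Tnni1 and Tnnc1 and the lipogenic genes Elovl6, Thrsp, Acly and Scd1 lie higher in the CR library, and Gadd45a, Ankrd1, Fbxo32, Trim63, Cdkn1a and Krt18 lie lower.

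Lipid synthesis genes were higher in the CR library. Of 19 lipogenesis genes, 14 were at least 2-fold higher, 1 was at least 2-fold lower and 4 lay within 2-fold. The list had a median log2 ratio of 2.45 (a fold of 5.48) at percentile 100. Elovl6 stood at 51.7 and 1488 FPKM and Thrsp, a regulator of lipogenesis (chromosome 7, 104561439 to 104566195), at 135 and 3303. Acly (chromosome 11, 100337666 to 100389314) stood at 181 and 3887, and the stearoyl-CoA desaturase Scd1 (chromosome 19, 44468940 to 44482473) at 1072 and 14907. The fatty acid synthase Fasn stood at 164 and 2041. The lower member was the glycerol-phosphate acyltransferase Gpam, at 2216 and 914 FPKM. White adipocyte markers were higher as well: 12 of 15 were at least 2-fold higher, 0 were at least 2-fold lower and 3 lay within 2-fold. Their median log2 ratio was 1.93 at percentile 100. The adipokines Retn and Adipoq stood at 48.6 and 1148 FPKM and 153 and 1178 FPKM, and the fatty acid binding protein Fabp4 at 2948 and 12924. The beta-3 adrenergic receptor Adrb3 was listed at 0 and 48.9. Car3, a carbonic anhydrase that muscle fibres also express, stood at 14545 and 17548, within 2-fold. The lipogenesis and white adipocyte lists share 1 gene, Agpat2. Of 9 brown adipocyte markers, 6 were at least 2-fold higher, 1 was at least 2-fold lower (Pank1, 260.4 and 129 FPKM) and 2 lay within 2-fold, with a median log2 ratio of 1.23 at percentile 99.98; without the markers listed at 0 in a library the median was 0.63. Ucp1, the uncoupling protein of brown fat, was listed at 0 and 189 FPKM, Otop1 at 0 and 96.8 and Prdm16 at 0 and 20.7. With a filter at a mean of 100 FPKM, added after the values were seen, the brown list lay within the random range (percentile 81.3, 5 genes).

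Cholesterol synthesis genes had a median log2 ratio of 0.47 at percentile 99.74, beside the adipocyte median of 1.93. Of 17 genes, 7 were at least 2-fold higher, among them the lanosterol synthase Lss (19.3 and 331 FPKM), 1 was at least 2-fold lower and 9 lay within 2-fold. Sc4mol was listed at 0 and 61.5 FPKM, and Fdft1, the squalene synthase, stood at 844 and 1112. Fatty acid uptake and oxidation genes did not stand apart (median 0.10, percentile 78): 4 of 31 were at least 2-fold higher, 2 were at least 2-fold lower and 25 lay within 2-fold. Lipe, the hormone-sensitive lipase, which is also in the adipocyte list, stood at 226 and 575 FPKM, and Angptl4, a lipoprotein lipase inhibitor, at 199 and 426. Fabp3, the fatty acid binding protein of muscle, stood at 10993 and 14719.

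Genes of oxidative phosphorylation were higher in the CR library by a smaller ratio. Of 54 nuclear-encoded genes 5 were at least 2-fold higher, 0 were at least 2-fold lower and 49 lay within 2-fold. The median log2 ratio was 0.45 (a fold of 1.36) at percentile 100. Ndufb3 and Ndufa5 of complex I stood at 613 and 1376 FPKM and 2882 and 6285 FPKM, Uqcrb of complex III at 4721 and 10576, and Atp5b of the ATP synthase at 24407 and 29552. The plus-strand and minus-strand loci that span the mitochondrial genome stood at 57901 and 104224 FPKM and at 41858 and 71609 FPKM, ratios of 1.80 and 1.71; as the kit as described does not mark strand, reads cannot be assigned between these overlapping loci and each value is uncertain. Slow-twitch genes (median 1.99), white adipocyte markers (1.93) and brown adipocyte markers (1.23) were higher in the same library; the brown list shares Cox8b (1697 and 3402 FPKM) and Cox7a1 (5588 and 6717) with this list. Tricarboxylic acid cycle genes lay within the random range, with 23 of 23 within 2-fold (median 0.26, percentile 94.56). Idh2 stood at 1354 and 2378 FPKM, Fh1 at 1794 and 3127 and Idh3b at 7176 and 9731. Glycolysis and glycogen genes lay within it too (median 0.25, percentile 92.92), with 2 of 20 at least 2-fold higher, the regulatory enzyme Pfkfb3 (518 and 1337 FPKM) and the muscle fructose bisphosphatase Fbp2 (877 and 1943). This list shares Pgam2 and Eno3 with the fast-twitch list. With random lists matched also on GC content, a setting added after the values were seen, both lists lay above the range, at percentiles 98.28 and 98.64. Mitochondrial ribosomal proteins had a median of 0.12 (percentile 93.88), with 1 of 43, Mrpl1 (442 and 1369.7), at least 2-fold higher. Cytosolic ribosomal proteins had a median of 0.36 at percentile 99.96. Of these, 2 of 40 were at least 2-fold higher, Rps14 (2011 and 4115) and Rpl37 (813 and 1651), Rpl17 was listed at 38.1 and 0, and 37 lay within 2-fold. These proteins have many processed pseudogenes, so their values are uncertain.

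Embryonic sarcomere and denervation genes were lower in the CR library. Of 18 measured genes 13 were at least 2-fold lower, 2 were at least 2-fold higher and 3 lay within 2-fold. This list had a median log2 ratio of -1.32 at percentile 0. Gadd45a (chromosome 6, 66985090 to 66987571) stood at 2088 and 279.9 FPKM, and the fetal acetylcholine receptor subunit Chrng was listed at 99.8 and 0. The transcription factor Runx1 stood at 448 and 75.1 and the acetylcholine receptor subunit Chrna1 at 727 and 263. The higher members were the cardiac actin Actc1 (3172 and 16539.9 FPKM), a close paralog of Acta1 whose value is uncertain for that reason, and Mybph (776 and 2302). Tendon markers were lower in the same library (median -1.18, percentile 0.05). Myogenic regulators and satellite cell genes lay just inside the random range (median -0.32, percentile 2.67) and below it in some other settings. In this list 3 of 13 were at least 2-fold lower, Myf6 (1824 and 563 FPKM), Myod1 (198 and 60.8) and Myog (395 and 174), which is also in the denervation list. Vcam1 was listed at 0 and 30.4, and Mef2c stood at 2394 and 2197.

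Ubiquitin-proteasome and atrophy genes were lower as a list by a small ratio, with a median log2 ratio of -0.18 at percentile 0.83. Of 36 genes 3 were at least 2-fold lower, 0 were at least 2-fold higher and 33 lay within 2-fold. The list was split, with 22 genes below 0 on the log2 scale and 14 above it. Among the 14 were the proteasome subunits Psmb7 (2828 and 4048 FPKM) and Psmb6 (1617 and 2281 FPKM), so proteasome genes were not lower throughout. The genes past 2-fold were the muscle ubiquitin ligases Fbxo32 (chromosome 15, 58007450 to 58046641; 2199.5 and 767 FPKM) and Trim63 (chromosome 4, 133870803 to 133886072; 4762 and 1738 FPKM) and the deubiquitinase Usp14 (822 and 387), while Psmd2 of the proteasome stood at 7028 and 5222. FoxO and fasting genes, which include Fbxo32, Trim63 and Gadd45a, lay within the random range (median -0.19, percentile 6), with 5 of 23 at least 2-fold lower, 2 at least 2-fold higher, and Pdk4, the pyruvate dehydrogenase kinase, at 8293 and 7279 FPKM. Glucocorticoid response genes had a median of -0.33 at percentile 0.5. Of 18 genes 1 was at least 2-fold lower, the cell cycle inhibitor Cdkn1a (701 and 165 FPKM), and 17 lay within 2-fold, among them Tsc22d3 (2510.0 and 1324) and Cebpd (90.7 and 47.2). The p53, DNA damage and senescence list, which shares Gadd45a and Cdkn1a with others, had a median of -0.48 at percentile 0.27, with 7 of 17 at least 2-fold lower and 0 at least 2-fold higher. Without genes listed at 0 its median was -0.25, at percentile 6.31 and so within the random range. Perp, which is also in the keratinocyte list, was listed at 34.6 and 0 FPKM, Bbc3 at 22.6 and 0, and Ccng1 stood at 3525 and 4869.9. Heat shock and chaperone genes had a median of -0.34 at percentile 0.73, with 4 of 16 at least 2-fold lower and 12 within 2-fold. Hspa1b was listed at 89.1 and 0 FPKM, Hspa4l stood at 89.0 and 34.6 and Hspb8 at 4690.0 and 2071, while Cryab stood at 10670.2 and 11325. With the filter at a mean of 100 FPKM the glucocorticoid, p53 and heat shock lists lay within the random range, at percentiles 7.35, 8.03 and 6.99. Tendon markers were also lower in the CR library (median -1.18), and slow-twitch genes (1.99) and white adipocyte markers (1.93) were higher. Whether a different makeup of the dissected tissue bears on the lists of this paragraph was not tested.

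Autophagy and lysosome genes lay within the random range (median -0.07, percentile 24.18). The autophagy kinase Ulk1 (1094 and 336 FPKM) and the receptor Sqstm1 (4259.6 and 1799) were the 2 of 24 at least 2-fold lower, and Atg5 (136 and 304) was the 1 at least 2-fold higher. Insulin, IGF and mTOR genes had a median of 0.05 (percentile 71.02), with 3 of 29 at least 2-fold higher, including Igf2 (238 and 556 FPKM) and Tsc1 (464 and 1015), and 1 at least 2-fold lower, Sesn2 (79.5 and 18.6). Sirtuin, AMPK and mitochondrial biogenesis genes had a median of 0.01 (percentile 54.27). Sirt6 (82.7 and 35.7 FPKM) was the 1 of 28 past 2-fold, while Sirt1 stood at 75.9 and 129, Prkaa2 of AMPK at 2911 and 3164 and the coactivator Ppargc1a at 902 and 488. All 19 circadian clock genes measured lay within 2-fold (median -0.14, percentile 14.05), with Per2 at 404 and 243 FPKM and Arntl at 334 and 220.5. Unfolded protein response genes had a median of -0.22 (percentile 8.31), with Psat1 listed at 0 and 125 FPKM and Xbp1 at 527 and 303. Antioxidant genes had a median of 0.02 (percentile 51.29), with heme oxygenase Hmox1 at 205 and 51.8, Srxn1 at 341 and 157 and Sod3 at 65.0 and 142. Immediate early genes, which respond to stress at dissection, had a median of -0.18 (percentile 21.46). Of these, 5 of 19 were at least 2-fold lower, among them Nr4a3 (199 and 36.3 FPKM), Junb (81.3 and 32.4) and Jun (718 and 309), and 1 was at least 2-fold higher.

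Complement and acute phase genes were higher in the CR library, with a median log2 ratio of 0.65 at percentile 99.95, beside the adipocyte median of 1.93. Of 15 genes 6 were at least 2-fold higher, 0 were at least 2-fold lower and 9 lay within 2-fold. The acute phase protein Orm1 stood at 62.9 and 868 FPKM, haptoglobin, Hp, at 48.2 and 303, and Cfd, adipsin, which is also in the adipocyte list, at 389 and 2275. Interferon response genes had a median of 0.60 at percentile 99.65, with 6 of 17 at least 2-fold higher and 1 at least 2-fold lower. Irf7 was listed at 0 and 41.9 FPKM, Usp18 at 0 and 30.4 and Ddx58 at 30.7 and 0, and B2m stood at 1073 and 2237. Fibroblast and collagen genes had a median of 0.40 at percentile 99.93, with 6 of 25 at least 2-fold higher, among them the matrix proteins Postn (38.6 and 187 FPKM) and Lum (128 and 570.2), and 1 at least 2-fold lower, the collagen crosslinking enzyme Lox (323 and 129). Smooth muscle and pericyte genes had a median of 0.67 at percentile 99.99, with 3 of 12 at least 2-fold higher, Myh11 (171 and 463 FPKM), Acta2 (339 and 813) and Tagln (209 and 458). Tendon genes were lower, with a median of -1.18 at percentile 0.05 and -0.70 without genes listed at 0. Of these, 6 of 11 were at least 2-fold lower, among them Fmod (844 and 373 FPKM), and Tnc, Chad and Col12a1 were listed at 223 and 0, at 85.0 and 0 and at 55.7 and 0.

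Mast cell markers had a median of 5.17 at percentile 99.76 over 5 genes, of which 4 were listed at 0 in one of the libraries: Cma1 at 0 and 51.5 FPKM, Kit at 0 and 56.9, Mcpt4 at 0 and 35.1 and Tph1 at 68.4 and 0. That median rests on the genes listed at 0: Gata2, the mast cell gene above 0 in both libraries, had a log2 ratio of 0.42. Endothelial genes (median 0.20, percentile 92.56), macrophage and monocyte genes (median 0.49, percentile 96.91), Schwann cell and nerve genes (median 0.48, percentile 95.81), B and plasma cell genes (median -0.99, percentile 2.56) and keratinocyte genes (median -4.22, percentile 10.29) lay within the random range. Without genes listed at 0 in a library the keratinocyte median was -0.51 and the macrophage median 0.19. Of these lists, the endothelial, Schwann cell, B and plasma cell and keratinocyte lists left the range in some other setting. Examples are Emcn (200.4 and 486 FPKM) and Tek (157 and 338) of endothelium, Mpeg1 (82.6 and 15.2) and Tyrobp (0 and 77.7) of macrophages and Pmp22 (178 and 351) of Schwann cells. Others are Cd74 (191 and 94.3) and H2-Ab1 (91.7 and 37.7) of antigen presentation, and Trp63 (665 and 129), Sbsn (55.3 and 0) and Sfn (17.7 and 0) of keratinocytes, of which Krt10 (16.5 and 43.1) was the one at least 2-fold higher. Of the lists with under 5 measured members, the neutrophil list had 4 (highest S100a8, 0 and 581 FPKM), the erythroid list 4 (Hba-a1, 15925 and 48110.1), the histone list 4 (Hist1h1c, 1185 and 871), the cartilage and bone list 2 (Alpl, 80.9 and 126) and the T and NK cell list 1 (Thy1, 43.9 and 75.4). Of 37 lists tested, 13 lay above and 6 below the range of random lists and 18 within it. Of as many lists of genes drawn at random, 1.85 would lie outside it. The lists share members and their genes can vary together, so that number is not a chance level for them. These percentiles describe the pair of libraries and do not measure variation between mice.

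**Figure D3:**
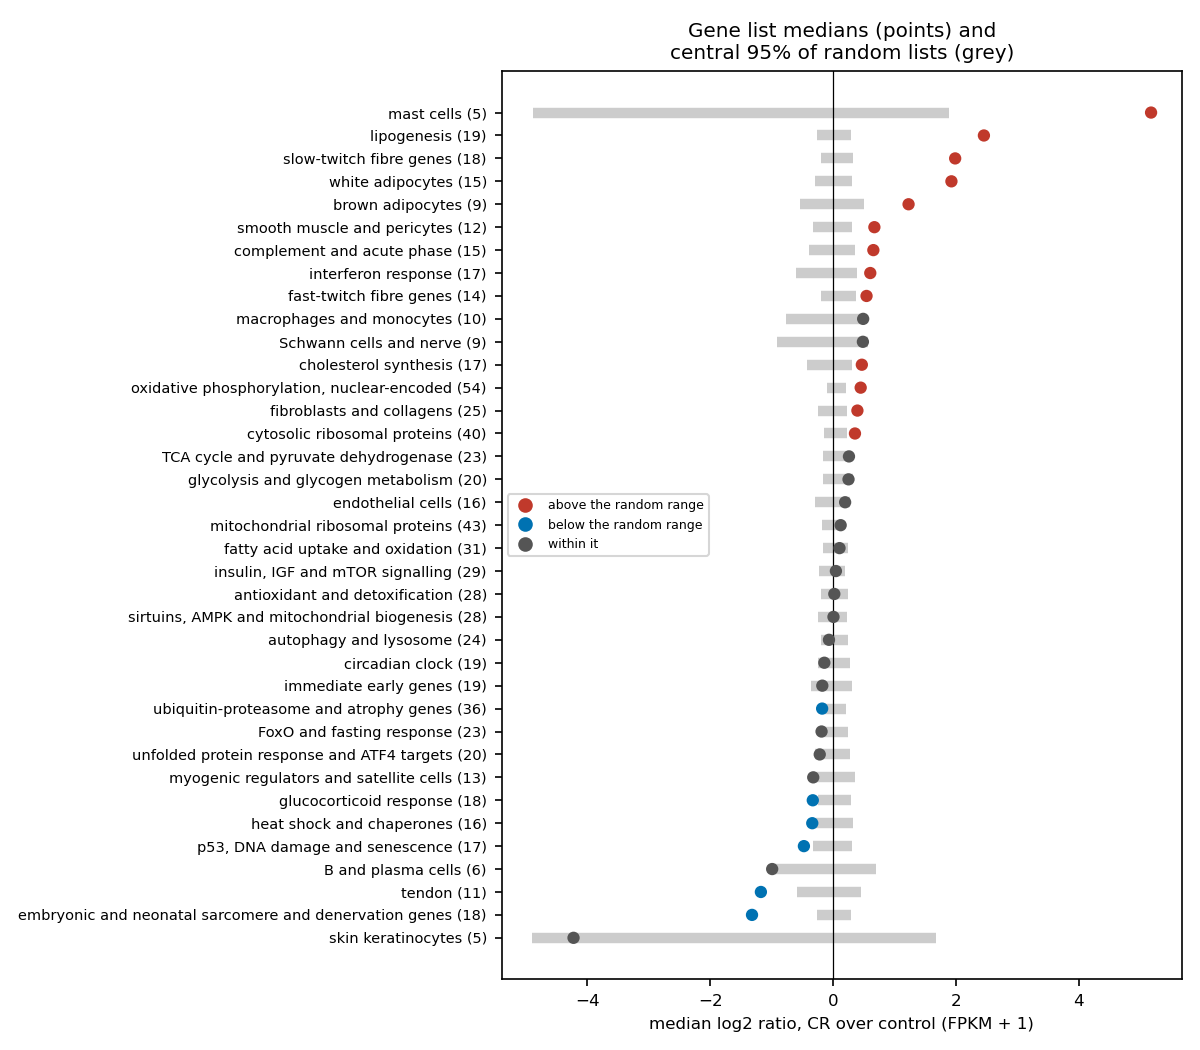
Median log2 ratio (CR over control) of each of the 37 gene lists tested, with the number of genes in brackets, as points, and the range that held all but 5% of 10000 random lists matched on mean FPKM as grey bars, 1 library per diet. The slow-twitch (1.99), lipogenesis (2.45) and white adipocyte (1.93) medians lie to the right of their bars and the denervation median (-1.32) to the left of its bar.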

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

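The settings that follow with filters at 100 and 300 FPKM, with genes at 0 left out, with a pseudocount of 50 FPKM and with matching on transcript length or GC content were chosen only after the result was seen; for the matching, the bounds used in the tests of the slow-twitch, lipogenesis and oxidative phosphorylation lists were set before the matched percentiles were seen. A filter at a mean of 100 FPKM left 390 higher and 417 lower genes of 7886, and a filter at 300 FPKM left 179 and 122 of 4170; both test fewer genes. Leaving out genes at 0 in either library left 674 lower genes (605 higher), and a pseudocount of 50 FPKM gave 385 higher and 442 lower. Under the filter at 100 FPKM the percentile moved to 7.35 for glucocorticoid response, 6.99 for heat shock, 8.03 for p53 and 81.3 for brown adipocytes, which then had 5 genes. Heat shock stood at percentile 6.22 under the filter at 300 FPKM and 3.74 with a pseudocount of 50 FPKM, and p53 at 6.31 without genes at 0. The filters leave fewer genes in these lists; for the pseudocount the cause was not tested. The other 15 of the 19 lists outside the random range kept their side in every setting that left at least 5 genes, including matching on transcript length and on GC content. Mast cells, 1 of these 15, were tested in 10 of 13 settings, as leaving out genes at 0, for example, left too few of their genes. In all, 438 of 463 list results kept their side, and 7 lists within the range left it in some setting. Of these, B and plasma cells and myogenic regulators, just inside the range, left it under several settings (lowest percentiles 1.09 and 1.51). Keratinocytes left it with a pseudocount of 50 FPKM (1.51) and with matching on length (1.39) or GC content (1.21), glycolysis (98.64) and the tricarboxylic acid cycle (98.28) with matching on GC content, endothelial cells (99.05) with the filter at 300 FPKM and Schwann cells (97.9) with a pseudocount of 50 FPKM. The others stayed within it in every setting that left at least 5 genes. Centring moved all log2 ratios by 0.03 and rescaling by -0.07. As centring moves every gene alike, it cannot change the percentile of a list, and its list results were fixed in advance. Of 1080 results for named genes, 1042 stayed on their side of 2-fold, 38 crossed it (29 of them with a pseudocount of 50 FPKM) and 0 changed direction. A change of pseudocount cannot reverse a ratio, and the shifts by centring and rescaling were small, so the lack of reversals was largely fixed in advance. The depth of the libraries is unknown, so the counting error of single genes could not be given. No paired analysis was possible because each group has 1 library.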

Other observations

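Of the tests reported here, those of library scaling, of the dissected fibre types, of adipocytes and of Tnnt2 alone were chosen only after the result was seen, as were the genes named in the next paragraph outside the rules. Matching on transcript length and on GC content was chosen after the list ratios were seen, with its bounds set before the matched percentiles were.

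The keratin Krt18 stood at 1158 and 201 FPKM in the control and CR libraries, and its partner Krt8 was listed at 425 and 0, where the 0 can be a failed estimate. Genes of the alpha and beta chains of haemoglobin stood higher, Hba-a1 at 15925 and 48110.1 FPKM and Beta-s at 7949 and 37468, while Hbb-b2 stood at 2514 and 2598; these copies are near-identical and their values are uncertain. Sbpl and Dcpp2, both on chromosome 17, stood at 48.3 and 2924 and at 0 and 297 FPKM. Among 12074 unnamed loci with a mean of at least 1 FPKM, 2063 were at least 2-fold higher in the CR library (569 listed at 0 in the control library) and 3923 at least 2-fold lower (2428 listed at 0 in the CR library). Unnamed loci held 46.0% of the FPKM sum in the control library and 42.4% in the CR library.

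Slow-twitch genes were higher in the CR library as a list. Matched on transcript length and on GC content, the lower of the list's percentiles was 100, which argues against either as the whole cause. One scaling factor per library would move the list and its random lists alike, while the list stood at percentile 100 among random lists matched on mean FPKM, which argues against scaling as the whole cause. Of 8 genes chosen beforehand as markers of heart 2 were listed, Tnnt2 and Pln, with a median CR value 0.937% of that of Tnnc1. The bound set beforehand asked for at least 3 listed genes. Tnnt2, cardiac troponin T, taken alone after its value was seen, was at 1.26% of Tnnc1 in the CR library and lower there (67.1 FPKM) than in the control library (139), but the heart-expressed Myh6 (1479.9 and 18349 FPKM) and Actc1 (3172 and 16539.9), whose values are uncertain because of close paralogs, were higher, so heart tissue stays open. A larger share of slow fibres in the dissected CR tissue predicts the list median of 1.99 as a response of the muscle to the diet does, and with 1 library per group these cannot be told apart. The fast-twitch list was not lower in the CR library (median 0.54, percentile 99.87, with 0 of 14 genes at least 2-fold lower). The fast myosin heavy chains could not be compared. The denervation list (-1.32) was lower in the CR library together with tendon markers (-1.18), and a different makeup of the dissected tissue was not tested for it and stays open.

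Lipogenic genes were higher in the CR library together with adipocyte genes. The lower percentile of the lipogenic list under matching on length and on GC content was 100, which argues against those as the whole cause. The 14 adipocyte markers outside the lipogenic list had a median log2 ratio of 1.89 (from -0.73 to 4.53 among those above 0 in both libraries, with Adrb3 listed at 0 and 48.9 FPKM), with Fabp4 at 2948 and 12924 FPKM, Cfd at 389 and 2275 and Adipoq at 153 and 1178, and the 18 lipogenic genes outside the adipocyte list a median of 2.17. By a bound set after the values were seen, adipocytes as the whole cause predict a marker median of at least 2.45, that of the lipogenic list. The marker median of 1.89 fell short of it, but the ratios of single markers spread widely. More adipocytes in the CR tissue may account for the pattern in part, and whether in full stays undecided. Lipid synthesis induced within fat or muscle cells stays open as well. With 1 library per group these cannot be told apart.

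Oxidative phosphorylation genes were higher by a small ratio, and ratios also followed transcript length: from the shortest to the longest of 5 equal groups of genes the median log2 ratio went from 0.12 through 0.01, -0.04 and -0.10 to -0.14. The median transcript length of the list was 1139 nt, within the shortest group, so length was a candidate explanation. Matched on length and on GC content, the lower of the list's percentiles was 99.99, which argues against either as the whole cause. A response to the diet, the higher share of slow fibre transcripts and more adipocytes (white list 1.93, brown list 1.23) all stay open for this list and were not tested. The brown list shares Cox8b and Cox7a1 with the oxidative phosphorylation list, and its median was 0.63 without genes listed at 0.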
